A study of Mus musculus with 8 samples.

How the data were processed

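Inguinal white adipose tissue (iWAT) of male mice on a high-fat diet was sequenced, 4 libraries of wild type (WT) and 4 of adipocyte KLF10 knockout (KLF10AKO). Per the labels, total RNA was poly(A)-selected on poly-T beads, fragmented, primed with random hexamers, and size-selected for fragments of 370 to 420 bp before PCR. Per the submitters' processing notes, HISAT2 2.0.5, featureCounts 1.5.0-p3 and edgeR 3.22.5 were used with the mm10 genome. The role of each tool, the annotation release and the strand setting are not given in the sources used here. The deposited values are FPKM, made by the authors, with the length of each gene beside them. FPKM times gene length was a whole multiple of a single step per library for 100% of the values, within 0.01 of a read, so whole reads were recovered. These reads came to 1.05 to 1.09 times the library size implied by the step in WT and to 0.901 to 0.939 times in KLF10AKO, so the authors' sizes had been scaled between samples. Recovered reads ranged from 15537863 to 17499132 per library. Gene identifiers matched the GENCODE M21 annotation in 99.8% of 54532 genes, and 98.3% of those matched had the same coordinates. Among 145 named genes, 33 overlap exons of another gene in that annotation and 12 those of another protein-coding gene.

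The groups were compared with limma 3.58.1 in R 4.3.3. The model (lmFit, then eBayes with trend) was fitted to log2(FPKM + 0.5) of 16012 genes whose mean FPKM over the 8 libraries was at least 0.5, with no covariate. P-values were two-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05. Klf10 and the other named genes also had exact two-sided permutation tests of their 8 values. The 32 gene lists, covering lipid metabolism, FOXO1 targets, cell types of the fat pad and stress responses, were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. They were tested again with an estimated correlation and with fry. The model, the filter, the threshold, the lists and the rule for naming genes were chosen before the data were examined. That rule took Klf10, Foxo1, Pnpla2, Lipe, Adipoq and Lep. It added the 10 protein-coding genes with the largest passing change in each direction whose 4 KLF10AKO values all lay above, or all below, the 4 WT values. It also added up to 4 members of each list, those of lowest p. Members named as exceptions to their list's direction (such as Prkacb, Adra2a, Fbxo32, Slc2a1, Des, Itgax, Ly6a, Ccl11, Ifi27l2a, Cdk1 and Fabp3) were chosen after their values were seen.

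For a gene at 0 in every library of a group, the fold is a lower bound against 3 reads over that group's 4 libraries. PCR reads carry no molecular identifiers, so floors cover counting error only, while the intervals of fold changes cover the spread between these libraries. The procedure was tested on simulated data built from the WT means. A single spread between replicates (dispersion 0.00496, the median over WT genes) was used for every gene and both groups. With 4 libraries against 4 it recovered 88% of 100 genes changed 2-fold and 64% of 100 genes changed 1.5-fold, with 1.94% of calls false and 0 in the wrong direction. A list shifted 2-fold was called, and 0 of the other lists were. These rates belong to that setting, with few changed genes and an equal spread, and need not hold for the real libraries. Each gene was also drawn independently, so the list result does not cover lists whose members move together. Differences between replicates exceeded counting noise in all 12 pairs of libraries within a group, by a mean squared z of 5.16 to 105. The lowest correlation of log2 values within a group was 0.931, and those between groups ran from 0.755 to 0.801.

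Alternatives tried were pseudocounts of 1 and 0.1, no filter, a minimum mean FPKM of 2, TPM, median-of-ratios scaling, quantile normalization and robust eBayes. Also tried were eBayes without trend, library weights, voom on recovered reads, a replicate block, each library left out in turn, a minimum log2 change of 1 and protein-coding genes alone. Further alternatives were chosen after seeing the data. Each library was scaled to the mean of 14 adipocyte markers found in no other list, KLF10AKO replicate 4 was used as the sole library of its group and assumed to vary like WT, and fry was run on the scaled values. Median-of-ratios factors came to 1 in all 8 libraries, so that alternative moved nothing. Lists of lymph node stroma and follicle genes, trophoblast genes, abundant placental genes, placental genes outside the trophoblast clusters and milk genes were written after the data were seen and serve the closing section alone. The interval of a difference between list medians came from 10000 draws of the genes with replacement, and genes are not independent replicates. Members absent from the table or under the filter were left out of list tests. All 8 sample columns entered the comparison.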

Results

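Messenger RNA of inguinal white adipose tissue (iWAT), the subcutaneous fat pad of the groin, was measured in male mice fed a high-fat diet (HFD). The 8 libraries fell into 2 groups, wild type (WT, n = 4) and mice in which adipocytes lack the zinc-finger transcription factor KLF10 (KLF10AKO, n = 4). Values were the authors' FPKM (fragments per kilobase of gene length scaled by a library size that they had adjusted between samples). The reads recovered from them came to 16145160, 17499132, 16359349 and 15537863 in WT replicates 1 to 4 and to 17372504, 17396282, 17021816 and 15900731 in KLF10AKO replicates 1 to 4. Mitochondrial transcripts took 4.82% ± 1.28 of the reads in WT (SD, n = 4) and 3.20% ± 0.305 in KLF10AKO (SD, n = 4). Between 22760 and 22877 genes were above 0 in the WT libraries and between 23739 and 24388 in the KLF10AKO libraries. The labels give no animal for each library, so p-values measure the spread between these libraries.

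The comparison asked which genes of iWAT differ in HFD-fed mice when adipocytes lack KLF10, in a study of FOXO1, KLF10 and fat breakdown. Klf10 (ENSMUSG00000037465, mm10 chromosome 15, 38291463 to 38300706, minus strand), the targeted gene, was read first. Its FPKM was 16.7, 18.2, 16.7 and 21.1 in WT replicates 1 to 4 and 9.39, 9.68, 9.75 and 9.59 in KLF10AKO replicates 1 to 4. The means were 18.2 ± 2.09 and 9.60 ± 0.157 (SD, n = 4 each). On the log2 scale Klf10 fell by 0.88 (standard error 0.0781, 95% interval -1.06 to -0.70, limma adjusted p = 8.96e-06). The exact two-sided permutation p of the 8 values was 0.0286, the smallest that 4 against 4 can give. Each value covers all 4179 annotated bases of the gene, so a deleted exon was not read on its own. When every library was scaled to 14 adipocyte markers, a scaling chosen after the data were seen, the Klf10 change turned to 0.66 (limma adjusted p = 8.16e-04).

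Adipocyte and lipid metabolism genes took a smaller share of the mRNA in KLF10AKO iWAT than in WT iWAT, and lymphocyte genes a far larger one. All 22 adipocyte markers fell, by a median of 3.25-fold, and the lipases Pnpla2 and Lipe fell with them, by 3.77-fold and 3.18-fold. All 18 B cell genes and all 23 T and NK cell genes rose, by medians of 97.3-fold and 28.9-fold, with list means far above WT in all 4 KLF10AKO libraries. Skeletal muscle genes were high in KLF10AKO replicates 1 to 3, where Tnnt3, a fast troponin, stood at 996, 748 and 1698 FPKM, against 3.11 in replicate 4 and 0.426 ± 0.161 in WT (SD, n = 4). Genes of placental trophoblast, among them the lactogen Prl3b1 at 12.8 ± 5.16 FPKM (SD, n = 4), were read in the WT libraries, and Prl3b1 had 0 reads in KLF10AKO.

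Of 16012 genes tested, 11893 (74.3%) passed, 6305 higher and 5588 lower in KLF10AKO. A difference of at least 4-fold was met by 1216 of the higher genes and 85 of the lower genes. The balance of directions followed the scaling: 53.0% of the passing genes were higher with FPKM as the authors scaled it, 63.4% with TPM, 41.2% with quantile normalization and 98.3% with scaling to adipocyte markers. These scalings shifted the median log2 change of all genes by 0.20, -0.20 and 1.37. With KLF10AKO replicate 4 as the sole library of its group, a choice added after seeing the data because its muscle genes were far lower than in the other 3, 9944 genes passed, 5187 higher and 4757 lower. Fold changes were fitted on log2(FPKM + 0.5), which understates them for genes of low level.

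**Figure D1:**
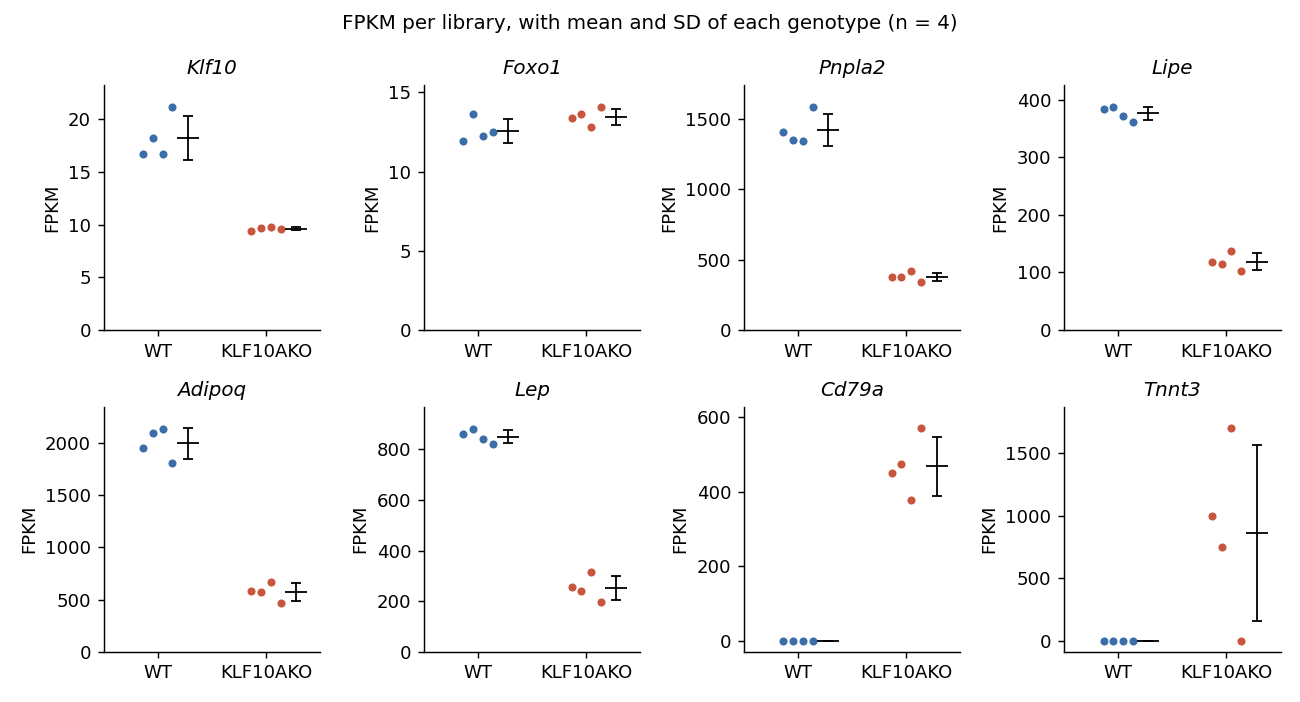
FPKM of Klf10, Foxo1, Pnpla2, Lipe, Adipoq, Lep, Cd79a and Tnnt3 in each library (vertical axes, FPKM; points, libraries; horizontal lines, group means, with SD as error bars, n = 4 per group). Pnpla2 lies at 1422 in WT and 377 in KLF10AKO on average, and Tnnt3 is near 0 in WT and at 3.11 in KLF10AKO replicate 4; scaled to adipocyte markers, Klf10 turns from a log2 change of -0.88 to 0.66.

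Pnpla2 (ENSMUSG00000025509, chromosome 7, 141455198 to 141460743, plus strand), which encodes adipose triglyceride lipase, the enzyme that starts triglyceride breakdown, stood at 1422 ± 112 FPKM in WT and 377 ± 30.2 in KLF10AKO (SD, n = 4 each). Its log2 change was -1.91 (standard error 0.0985, adjusted p = 3.55e-07), and -0.32 after scaling to adipocyte markers (adjusted p = 0.0133). Lipe (ENSMUSG00000003123, chromosome 7, 25379527 to 25398710, minus strand), hormone-sensitive lipase, stood at 376 ± 11.5 and 118 ± 14.7 FPKM. Its log2 change was -1.67 (standard error 0.0923, adjusted p = 5.36e-07), and -0.08 after that scaling, which no longer passed. Foxo1 (ENSMUSG00000044167, chromosome 3, 52268336 to 52353221, plus strand), the forkhead factor of the study's title, did not pass: 12.6 ± 0.761 FPKM in WT and 13.5 ± 0.513 in KLF10AKO, a log2 change of 0.10 (95% interval -0.04 to 0.23, adjusted p = 0.169). Foxo1 passed with TPM at 0.30, with library weights at 0.13 and with scaling to adipocyte markers at 1.63. The adipokine genes Adipoq (ENSMUSG00000022878, chromosome 16, 23146536 to 23158028, plus strand) and Lep (ENSMUSG00000059201, chromosome 6, 29060220 to 29073877, plus strand) stood at 2000 ± 148 and 851 ± 25.5 FPKM in WT and at 574 ± 85.3 and 252 ± 48.9 in KLF10AKO. Their log2 changes were -1.81 (standard error 0.131, adjusted p = 2.49e-06) and -1.77 (standard error 0.134, adjusted p = 3.27e-06), and -0.21 and -0.18 after the marker scaling, whose 14 markers include both.

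Each of 32 gene lists was set against all other genes with camera at a preset correlation. Counts adjusted over the list alone equalled those over all genes tested except where a second count is given. Camera placed 23 of 32 lists past the threshold; with an estimated correlation it placed 0 there, with 3 at an unadjusted p under 0.05, and fry, which asks only whether a list moves one way, placed 31. Each list median is also given after scaling to adipocyte markers, where most of the lower lists turned to higher. Of the 22 adipocyte markers, 14 set that scaling, so their own values after it lie near 0 by construction.

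Of the 22 adipocyte markers, which include Adipoq, Lep and Cebpa, a transcription factor of adipocyte differentiation at a log2 change of -1.84, 0 were higher and 22 lower (median -1.70, -0.10 after marker scaling). The list's adjusted p was 7.69e-09, and adjusted p = 0.293 with an estimated correlation. In the same KLF10AKO libraries 1 to 4, mean marker log2 levels lay at -1.60, -1.66, -1.39 and -1.89 of WT, while those of B cell genes lay at 6.44, 6.52, 6.17 and 6.71. Of 19 lipolysis enzymes and activators 17 fell and 2 rose (median -1.62, -0.02 after marker scaling, adjusted p = 5.27e-06, and adjusted p = 0.293 with an estimated correlation). Abhd5, the co-activator of adipose triglyceride lipase, changed by -2.09, the carboxylesterases Ces1f and Ces1d by -1.81 and -1.62, and the natriuretic peptide receptor Npr1 by -1.37 (0.17 after marker scaling). Among the exceptions was Prkacb, a catalytic subunit of protein kinase A, at 0.57. The genes that restrain lipolysis fell as well, 14 of 15 (median -1.71, -0.18 after marker scaling, adjusted p = 1.15e-05, and adjusted p = 0.293 with an estimated correlation). Among them were Adora1, the adenosine A1 receptor, at -2.20, the droplet coat protein gene Plin1 at -1.77, Sncg at -1.87 and the lipase inhibitor G0s2 at -1.46 (0.14 after marker scaling), while the adrenergic receptor Adra2a rose by 1.09.

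Among 26 FOXO1 target genes 18 fell and 7 rose (median -0.79, 0.77 after marker scaling, adjusted p = 0.00533, and adjusted p = 0.302 with an estimated correlation). Zbtb16 changed by -2.10 and Pck1, the enzyme of glyceroneogenesis, by -1.45 (0.14 after marker scaling), while the stress gene Sesn1 and the muscle atrophy gene Fbxo32 rose by 0.89 and 1.95. The means of this list in KLF10AKO libraries 1 to 4 lay at -0.46, -0.50, -0.30 and -0.75 of WT, and with replicate 4 alone, where skeletal muscle genes were lowest, 3 of its genes were higher and 16 lower. All 25 genes of fatty acid and triglyceride synthesis fell (median -1.50, 0.02 after marker scaling, adjusted p = 1.06e-08, and adjusted p = 0.293 with an estimated correlation). Agpat2 and Dgat2, which build triglyceride, changed by -2.07 and -1.91, and the ketone-using enzyme Aacs by -1.82. Their regulator Srebf1 changed by -1.11 (0.46 after marker scaling). Cholesterol synthesis was split, with 14 of 21 genes lower and 4 higher (median -0.45, 0.88 after marker scaling, adjusted p = 0.0279, and adjusted p = 0.302 with an estimated correlation). Insig1, which holds back sterol regulatory factors, changed by -2.33, whereas the factor gene Srebf2 rose by 1.33. The synthase gene Hmgcs1 and the desaturase gene Sc5d changed by -1.34 and -1.33 (each 0.23 after marker scaling).

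**Figure D2:**
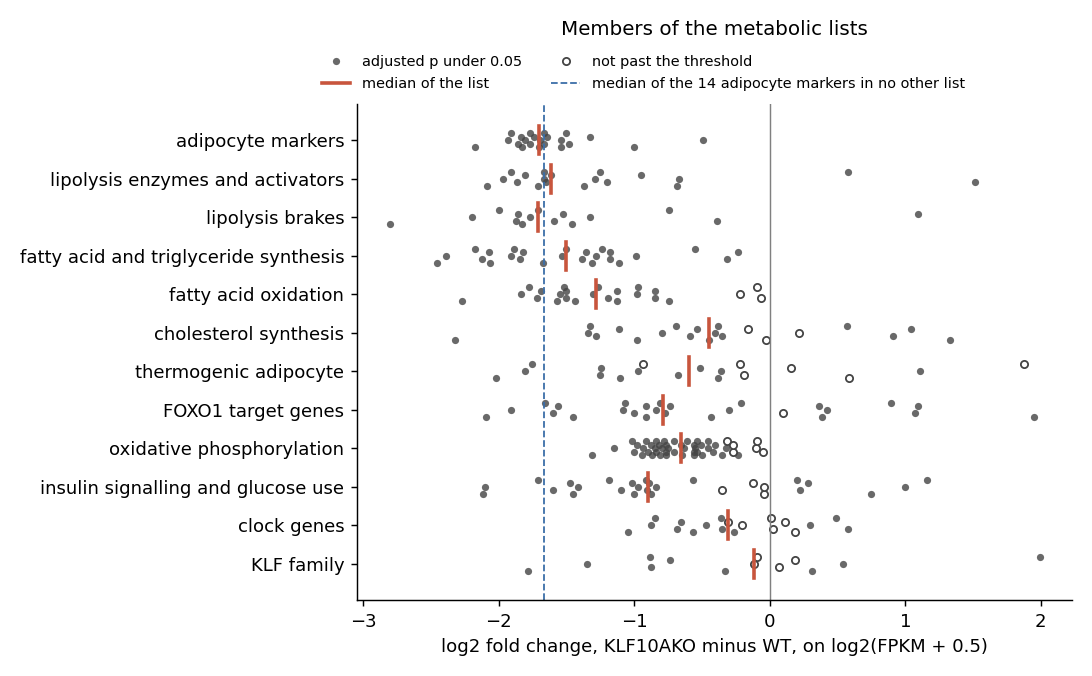
Log2 fold change of each member of 12 gene lists (horizontal axis, log2, KLF10AKO minus WT; filled points, adjusted p under 0.05; open points, not past it; red line, list median; dashed line, median of 14 adipocyte markers, -1.67). The medians of the lower lists lie between 0 and the marker line or close to it, and after scaling to these markers the lipolysis list lies at -0.02 and the list of fatty acid oxidation turns to 0.21.

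Genes of fatty acid oxidation fell in 21 of 24 cases with 0 higher (median -1.29, 0.21 after marker scaling, adjusted p = 2.47e-08, and adjusted p = 0.293 with an estimated correlation). The peroxisomal gene Ehhadh changed by -2.27, and the carnitine transferase gene Cpt2 by -1.69. Of 49 subunits of oxidative phosphorylation 43 fell and 0 rose (median -0.65, 0.90 after marker scaling, adjusted p = 9.04e-08, and adjusted p = 0.378 with an estimated correlation). Atp5b of ATP synthase changed by -1.31 (0.28 after marker scaling) and Ndufa10 of complex I by -0.87 (0.71 after marker scaling, where all 49 members rose). The list means in KLF10AKO libraries 1 to 4 lay at -0.63, -0.65, -0.43 and -0.89 of WT, in the order of both adipocyte marker and skeletal muscle means, and with replicate 4 alone the median was -0.91. Of 18 thermogenic genes 11 fell and 1 rose (median -0.59, 0.70 after marker scaling, adjusted p = 0.0124, and adjusted p = 0.293 with an estimated correlation), with Cidea at -2.02 and the potassium channel gene Kcnk3 at -1.76. The means of this list in KLF10AKO libraries 1 to 4 lay at -0.43, -0.48, -0.23 and -1.02 of WT, the lowest in the library with the lowest muscle genes, and its muscle-expressed member Fabp3 stood at 1.87 without passing. Insulin signalling and glucose use had 18 of 28 genes lower and 6 higher (median -0.90, 0.64 after marker scaling, adjusted p = 0.00120, and adjusted p = 0.293 with an estimated correlation). Grb14, an adaptor of the insulin receptor pathway, changed by -2.10, and the glucose transporter gene Slc2a1 rose by 1.16.

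Of 22 genes of oxidative stress defence 18 fell and 1 rose, with 19 and 1 when adjusted over the list alone (median -0.77, 0.78 after marker scaling, adjusted p = 7.35e-05, and adjusted p = 0.302 with an estimated correlation). The extracellular dismutase gene Sod3 changed by -1.75 and the haem oxygenase gene Hmox1 by -1.14 (0.42 after marker scaling). The unfolded protein response did not pass as a list (11 of 22 lower and 5 higher, 12 and 6 when adjusted over the list alone, median -0.18, 1.30 after marker scaling, adjusted p = 0.0824), although Asns, asparagine synthetase, changed by -1.62 and Xbp1 by -1.01 (0.57 after marker scaling).

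Of the 32 lists, that of B cell genes had the highest median. Cd79a and Cd79b, the signalling chains of the B cell receptor, went from 0.813 ± 0.162 and 1.01 ± 0.240 FPKM in WT to 468 ± 79.7 and 328 ± 54.4 in KLF10AKO (SD, n = 4 each), log2 changes of 8.47 and 7.76. Ighd, the heavy chain of immunoglobulin D on naive B cells, changed by 7.92. Among the 10 protein-coding genes with the largest rises were also Ly6d at 8.01, Fcmr at 7.45, Fcer2a at 7.07 and Ltb at 7.04, all known from lymphocytes. The list median of 18 B cell genes was 6.60 (7.55 after marker scaling, adjusted p = 4.38e-11, and adjusted p = 0.293 with an estimated correlation). All 23 T and NK cell genes rose, at a median of 4.85 (5.89 after marker scaling, adjusted p = 4.38e-11, and adjusted p = 0.293 with an estimated correlation). Ccr7, a mark of naive and central memory T cells, changed by 6.29, Cd8a by 6.28 and the kinase gene Lck by 5.62. Ccl21a, the chemokine that draws T cells and dendritic cells into lymph nodes, had 0 reads in WT and 29.8, 34.5, 80.2 and 244 FPKM in KLF10AKO libraries 1 to 4, at least 797-fold higher against a floor of 3 reads over the 4 WT libraries, and at least 395-fold without KLF10AKO replicate 4. It lies on the unplaced scaffold JH584294.1 and has near-identical copies, so its level is uncertain. In KLF10AKO replicate 4 alone the B and T cell medians were 6.85 and 5.12.

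Interferon response genes rose in 20 of 22 cases (median 1.55, 3.07 after marker scaling, adjusted p = 2.54e-06, and adjusted p = 0.302 with an estimated correlation). Mx1, an antiviral GTPase gene, changed by 4.57, Usp18 by 2.98 and the transcription factor gene Irf7 by 2.45, while Ifi27l2a fell by 1.34. The means of this list in KLF10AKO libraries 1 to 4 lay at 1.55, 1.60, 1.37 and 1.76 of WT. B cell genes had the same order (6.44, 6.52, 6.17 and 6.71). Adipocyte marker and skeletal muscle means had exactly the reverse order, so the order does not single out B cells. Inflammatory cytokines and chemokines rose in 12 of 24 cases and fell in 8, without passing as a list (median 0.54, 1.56 after marker scaling, adjusted p = 0.237). Cxcl13, the chemokine of B cell follicles, went from 0.582 ± 0.0524 to 84.3 ± 14.3 FPKM (SD, n = 4 each), a log2 change of 6.28, Ccl5 changed by 4.91 and Cxcl10 by 3.13, and the eosinophil chemokine gene Ccl11 fell by 1.36. Of 24 macrophage genes 9 rose and 11 fell, 9 and 12 when adjusted over the list alone, and the list did not pass (adjusted p = 0.710). Its median was -0.19 (1.27 after marker scaling, with 22 of 24 genes higher) and its mean 0.25, and camera placed it lower while fry placed it higher. Timd4, a receptor of resident macrophages, changed by 5.19 and Ctss by 1.68, while the scavenger receptor gene Cd163 changed by -1.66. Genes of lipid-associated macrophages fell in 18 of 19 cases (median -1.27, 0.21 after marker scaling, adjusted p = 7.35e-05, and adjusted p = 0.336 with an estimated correlation). Their members Fabp5 and Lpl, both also made by adipocytes, changed by -1.69 and -1.83, and Itgax rose by 0.41. The means of this list in KLF10AKO libraries 1 to 4 lay at -1.06, -1.15, -0.72 and -1.69 of WT. They had the order of both adipocyte marker and skeletal muscle means, and with replicate 4 alone the median was -1.88. Neutrophil and mast cell genes rose in 7 of 11 cases and fell in 3 (median 0.64, 1.81 after marker scaling, camera adjusted p = 0.300). The mast cell protease gene Mcpt4 changed by 1.75. Neutrophil genes went both ways, with the receptor gene Cxcr2 at 2.59 and S100a8 at -2.16.

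**Figure D3:**
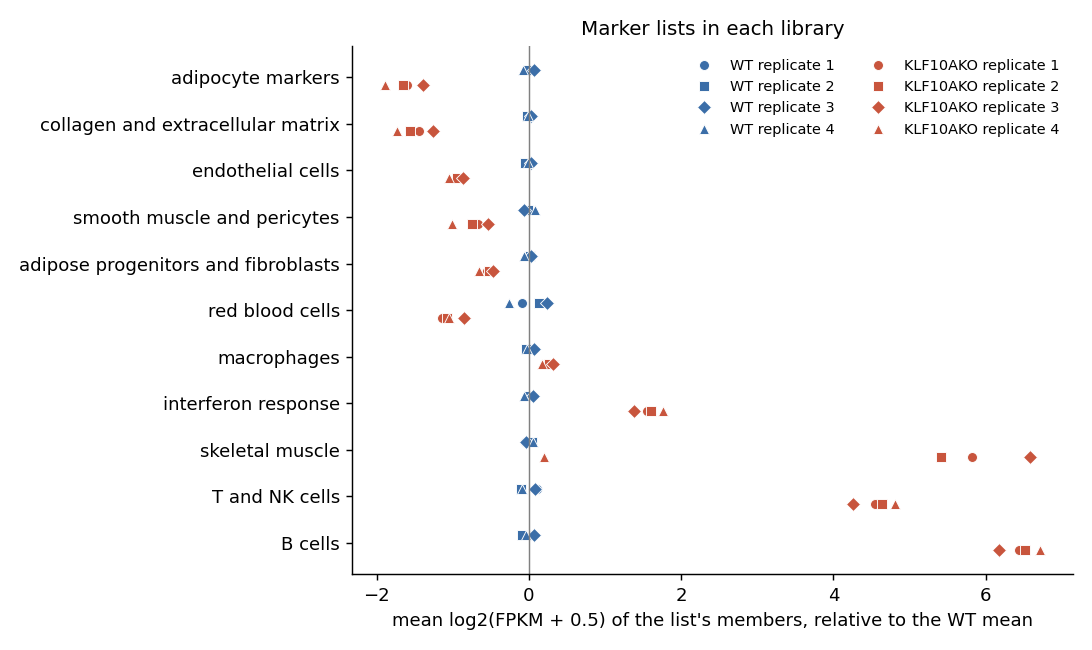
Mean log2(FPKM + 0.5) of 11 marker lists in each library, relative to the WT mean (horizontal axis, log2; a symbol for each replicate). B cell genes lie between 6.17 and 6.71 in the KLF10AKO libraries, skeletal muscle genes at 5.82, 5.42, 6.58 and 0.19, and adipocyte markers between -1.89 and -1.39; after marker scaling the medians of endothelial, smooth muscle, fibroblast, red cell and macrophage genes turn positive.

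Skeletal muscle genes rose in 19 of 22 cases, 20 when adjusted over the list alone, with 0 lower (median 4.66, 6.09 after marker scaling, adjusted p = 0.00572, and adjusted p = 0.537 with an estimated correlation). Tnni2, fast troponin I, stood at 574, 429, 1021 and 1.85 FPKM in KLF10AKO libraries 1 to 4 and at 0.258 ± 0.0986 in WT (SD, n = 4). The muscle enolase gene Eno3 changed by 4.20 with all 4 KLF10AKO libraries and by 1.55 with replicate 4 alone, and Tnnt3 by 8.15 and 1.98. With replicate 4 alone the list median was 0.20, with 10 genes higher and 5 lower, and with voom neither Tnnt3, Tnni2 nor the list passed.

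Of 30 collagen and matrix genes 30 fell (median -1.66, -0.08 after marker scaling, adjusted p = 1.38e-10, and adjusted p = 0.293 with an estimated correlation), with the basement membrane collagen gene Col4a1 at -1.95 and Col5a2 at -1.91. Progenitor and fibroblast genes fell in 16 of 21 cases and rose in 4 (median -0.93, 0.58 after marker scaling, adjusted p = 0.00533, and adjusted p = 0.293 with an estimated correlation). The preadipocyte factor gene Zfp423 changed by -1.37 (0.11 after marker scaling), and those that rose were Dpp4 at 2.98, Icam1 at 1.60, Cd55 at 1.54 and Ly6a at 0.56, all also found on lymphocytes. The TGF-beta response did not pass (12 of 26 lower and 6 higher, median -0.28, 1.28 after marker scaling, adjusted p = 0.111). Its members Acta2 and Pmepa1 changed by -2.24 and -1.45 (Pmepa1 0.14 after marker scaling), and Id2 and the ligand gene Tgfb1 rose by 1.71 and 1.12.

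Endothelial genes fell in 16 of 17 cases (median -1.10, 0.49 after marker scaling, adjusted p = 1.01e-06, and adjusted p = 0.293 with an estimated correlation), with Tek and Tie1, receptors of the angiopoietin system, at -1.33 and -1.28 (0.19 and 0.28 after marker scaling). Smooth muscle and pericyte genes fell in 11 of 14 cases (median -0.95, 0.54 after marker scaling, adjusted p = 2.27e-04, and adjusted p = 0.293 with an estimated correlation). Cspg4 of pericytes changed by -2.05, and the single riser was Des, desmin, which skeletal muscle also makes, at 3.45. All 5 red cell genes fell (median -0.996, 0.53 after marker scaling, adjusted p = 0.0167, and adjusted p = 0.302 with an estimated correlation). These include the globin genes Hbb-bt and Hbb-bs at -1.17 and -1.07 (0.41 and 0.53 after marker scaling), whose copies share reads, so that their levels are uncertain. Schwann cell genes fell in 7 of 11 cases and rose in 3 without passing as a list (median -0.81, 0.25 after marker scaling, adjusted p = 0.154), with S100b at -2.69 and Cnp at 2.12. The epithelial list had only 3 measured genes, 1 higher and 2 lower (median -0.56, 0.58 after marker scaling, adjusted p = 0.596): Epcam at 1.81, Krt10 at -0.56 (0.58 after marker scaling), and the milk protein gene Wap, which went from 2.97 ± 1.39 to 0.0137 ± 0.0273 FPKM (SD, n = 4 each), a single read in KLF10AKO.

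Immediate early and stress genes rose in 16 of 24 cases and fell in 4 (median 0.75, 2.04 after marker scaling, adjusted p = 0.0136, and adjusted p = 0.293 with an estimated correlation), with Egr3, Myc and Egr1 at 3.73, 2.26 and 1.86. Cell cycle genes rose in 13 of 24 cases (median 0.34, 1.60 after marker scaling, adjusted p = 0.0168, and adjusted p = 0.455 with an estimated correlation). The helicase subunits Mcm5 and Mcm3 changed by 2.03 and 1.66, and the mitotic kinase gene Cdk1 fell by 0.77. The means of the cell cycle list in KLF10AKO libraries 1 to 4 lay at 0.50, 0.59, 0.42 and 0.68 of WT, those of B cell genes at 6.44, 6.52, 6.17 and 6.71. Here too, adipocyte marker and skeletal muscle means ran in the reverse order. Clock genes did not pass as a list (10 of 19 lower and 3 higher, median -0.31, 1.17 after marker scaling, adjusted p = 0.0616), with Cry2 and Per3 at -0.88 and -0.85 (0.63 and 0.59 after marker scaling). Nor did the KLF family (6 of 13 lower and 3 higher, median -0.12, 1.11 after marker scaling, adjusted p = 0.275), in which Klf9 and Klf14 changed by -1.79 and -1.35 and Klf2, abundant in endothelium and resting lymphocytes, rose by 1.99.

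The 10 protein-coding genes with the largest falls began with 7 genes of placental trophoblast that had reads in all 4 WT libraries and 0 reads in the 4 KLF10AKO libraries. Against a floor of 3 reads over the KLF10AKO libraries, Prl3b1 was at least 335-fold lower, Tpbpa at least 440-fold, Tpbpb at least 257-fold and Ceacam11 at least 225-fold. Psg23 was at least 205-fold lower, Prl8a9 at least 155-fold and Prl8a6 at least 151-fold. Their WT means lay between 3.82 FPKM (Psg23) and 12.8 FPKM (Prl3b1). These genes belong to families of similar copies whose reads can be shared, so the level of each is uncertain. The remaining 3 were Tph2, the neuronal tryptophan hydroxylase, at -2.93 (13.1 ± 1.08 to 1.36 ± 0.633 FPKM), Hcar1, the lactate receptor of adipocytes, at -2.81 (26.2 ± 2.14 to 3.41 ± 1.03 FPKM), and S100b at -2.69 (12.96 ± 1.56 to 1.59 ± 0.316 FPKM, SD, n = 4 for each group).

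Intervals and floors cover counting error or the spread between these libraries, not differences in the tissue sampled. The genes Foxo1, Lipe and Srebf1 and others named here overlap exons of a gene on the opposite strand, and the strand setting of the counts was not given in the sources used here, so overlapping reads are uncertain.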

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

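Of the tests below, the splits of the samples were chosen before the result was seen, and all others after it. Each named gene, list mean and library value was checked within each genotype for a library far from the other 3. Of 354 such checks of 4 libraries, 18 (5.08%) held one, and independent checks would give about 18 at 1 in 20. These checks share the same 8 libraries and their genes overlap between lists. The rate therefore does not show that any library flagged below arose by chance. The real grouping called 11893 genes, and 1 of the 35 splits of the 8 libraries into 4 and 4, the real one, called as many. The highest count of the other splits was 2. Each of those splits mixes WT and KLF10AKO libraries, so differences between the groups widen its spread and lower its count. The splits therefore do not exclude chance, and they cannot tell the genotype from a difference in tissue makeup along the groups.

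KLF10AKO replicate 4 stood apart in Tnnt3 at 3.11 FPKM (748 to 1698 in the other 3), Tnni2 at 1.85 (429 to 1021), the oxidation gene Ehhadh at 5.32 (7.50 to 7.64) and the clock gene Per3 at 2.996 (3.601 to 3.67). KLF10AKO replicate 3 stood apart in Kcnk3 at 4.91 FPKM (3.90 to 4.01) and in Wap at 0.0547, a single read where the others had 0. WT replicate 4 stood apart in Dgat2 at 268 FPKM (333 to 346), Cpt2 at 68.5 (74.7 to 75.9), Tgfb1 at 16.4 (13.5 to 13.97) and Cd163 at 10.02 (11.6 to 11.8). It did so also in the mast cell gene Tpsb2 at 4.60 FPKM (6.87 to 7.40) and in Sod3 at 399 (346 to 352). WT replicate 2 stood apart in Fcmr at 0.0693 FPKM (0.499 to 0.578), in Aacs at 61.3 (54.2 to 55.1) and in mitochondrial reads at 2.91% (5.24% to 5.60%). WT replicate 3 stood apart in Hba-a1 at 458 FPKM (312 to 332), and WT replicate 1 in Clock at 6.07 (5.72 to 5.75) and in Gm23935 at 76877 (1022 to 1822).

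Lipolysis genes fell in KLF10AKO together with the rest of the adipocyte genes. If the KLF10AKO libraries held less adipocyte RNA, lipolysis genes and adipocyte markers of no other list should fall alike, and the median of the 19 lipolysis genes lay 0.055 (log2) above that of the 14 markers, with a 95% interval of -0.15 to 0.50 from drawing genes again; the medians of 5 of 30 other lists fell in that interval. That is consistent with less adipocyte RNA as a source of the fall of the set, though after scaling to the markers 6 members were higher and 4 lower. Loss of KLF10 in adipocytes stays open too: Pnpla2 lay at -0.318 after scaling to the markers (adjusted p = 0.0133), within the markers' SD of 0.351 and outside the SD of 0.169 without Cfd, and since genotype and tissue makeup change together and the markers may respond to the genotype, the explanations cannot be told apart.

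B and T cell genes rose in all 4 KLF10AKO libraries, and 12 of 15 tested genes of lymph node stroma and follicles rose with them. Glycam1, Madcam1, Chst4 and Ccl21a, genes of node vessels and stroma, were all higher, 4 of 4, which argues against scattered lymphocytes without lymphoid tissue as the whole source. Of the 15, the B cell list also holds Cr2 and the cytokine list Cxcl13, WT fat itself expressed Clu, Enpp2 and Ltbr, of which Enpp2 and Ltbr were lower in KLF10AKO, and Pdpn did not pass at 0.21 (adjusted p = 0.0583). Glycam1 went from 0.427 to 30.2 FPKM and Clu from 4.60 to 138, which makes lymph node tissue in the KLF10AKO libraries a candidate source. The inguinal fat pad can hold the inguinal lymph node. The node's presence in the dissected tissue could therefore differ along with the genotype, which was not tested. Lymphoid tissue formed in the fat itself, and any effect of the genotype, stay open as untested.

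Trophoblast genes were read almost wholly in WT, 17 genes picked for reads in WT and almost none in KLF10AKO, with 6533 reads (1346, 1618, 1008 and 2561 in WT replicates 1 to 4) against 2 in KLF10AKO. Those 2 reads are 0.0805% of the 2484 that the adipocyte marker ratio gives. For these genes the gap is larger than that ratio gives. They were picked for it, so it is no independent test of less adipocyte RNA in the KLF10AKO libraries as the source. Of the 17 genes, 9 lie on chromosome 13 and 8 on chromosome 7 between 17074040 and 18656725. Those on chromosome 13 fall in separate stretches, the Prl genes between 27241847 and 27564606. Tpbpb, Tpbpa, Ctsj and Cts3 lie between 60901188 and 61570127. Placental RNA in the WT libraries stays open. Of 6 placental genes outside these stretches with at least 10 WT reads, 3 had under 0.1 of the KLF10AKO reads that the marker ratio gives. These were Rhox6, Rhox9 and Doxl2, with WT and KLF10AKO reads of 17 and 0, 38 and 0, and 54 and 0. The other 3 did not, with 14 and 13 for Ascl2, 12 and 22 for Syna and 5532 and 2742 for Peg10. A further 5 placental genes had at most 8 WT reads. A gene with another source in the KLF10AKO tissue would miss that mark whether or not WT held placental RNA. Ascl2, Syna and Peg10, read in both groups, therefore cannot decide the question. Any effect of the genotype on the trophoblast genes stays open as untested.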

How the results depend on the processing

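Scaling to adipocyte markers and KLF10AKO replicate 4 alone were chosen after seeing the data; the other settings were planned. In every planned setting that tested them, 140 of 145 named genes (not Foxo1, Tnnt3, Tnni2, Mylpf and Mybpc2) and 1 of 32 lists (epithelium) kept their direction and side of the threshold; the others lost or gained a call under the estimated correlation or fry. Leaving out each library in turn gave 11298 to 11862 genes past the threshold, 5991 to 6269 higher, 5307 to 5593 lower, 23 to 24 lists and Klf10 at -0.92 to -0.81; the clock list passed without WT replicate 3 or KLF10AKO replicate 3. The replicate number as a block gave 11726 genes, 6220 higher and 5506 lower; residuals of libraries sharing a number correlated by 0.00300 to 0.0310, and 6 of 8 libraries correlated best with their own number. With an absolute log2 change of at least 1, 4706 genes passed, 2823 higher and 1883 lower, as that setting removes small changes.

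With an estimated correlation 0 lists passed by camera, 3 at an unadjusted p under 0.05, while fry passed 31; under fry the macrophage list turned to a mean of 0.25. The estimated correlation was 0.943 for skeletal muscle, 0.720 for oxidative phosphorylation, 0.631 for adipocyte markers and 0.580 for B cells, against the preset 0.01. For progenitors and fibroblasts it was -6.76e-04 and for immediate early genes -8.51e-04, both below the preset. Those lists lost their calls too, and their unadjusted camera p rose from 0.00282 to 0.0170 and from 0.00851 to 0.0267. A higher correlation widens camera's test, but it cannot account for the rise in these lists. The cause of the lost calls was not tested. Over all settings the adjusted p of Foxo1 ran from 6.49e-07 to 0.830, that of Klf10 from 2.22e-06 to 0.00864, that of Pnpla2 from 2.67e-08 to 0.0133, that of Tnnt3 from 3.17e-08 to 0.178 and that of Tnni2 from 3.70e-08 to 0.275. With KLF10AKO replicate 4 alone 20 lists passed; those of cholesterol synthesis, immediate early genes, red cells and skeletal muscle did not, and the clock list did.

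Scaled to adipocyte markers, 13816 genes were higher and 236 lower, and 16 lists passed. By construction this scaling raised all genes of KLF10AKO, by a median of 1.37, and these log2 changes turned positive. Klf10 0.66; Acp5 0.32, Ctsb 0.21, Xbp1 0.57, Hmox1 0.42, Prdx6 0.25, Krt10 0.58 and Pmp22 0.0566. Lipid genes: Npr1 0.17, G0s2 0.14, Pck1 0.14, Srebf1 0.46, Sc5d 0.23, Hmgcs1 0.23, Eci1 0.04, Ebf2 0.17 and Pfkfb3 0.11. Respiratory genes: Atp5b 0.28, Sdha 0.58, Ndufb3 0.44 and Ndufa10 0.71. Stromal and vessel genes: Zfp423 0.11, Pmepa1 0.14, Sox18 0.41, Tie1 0.28, Tek 0.19, Robo4 0.66, Mcam 0.19 and Pdgfrb 0.46. Red cell genes: Hbb-bt 0.41, Hbb-bs 0.53, Hba-a1 0.60 and Alas2 0.42. Clock genes: Cry2 0.63, Per3 0.59, Clock 0.78 and Per2 0.83. With no filter 13624 genes passed, and 9300 at a mean FPKM of at least 2.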

Other observations

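Some genes fell further than any of the 14 adipocyte markers, whose changes ran from -1.93 (Pparg) to -0.49 (Cfd). Chosen after their values were seen, 101 passing genes lay below every marker. Of these, 93 (84 protein-coding, 26 in the fixed lists) also passed as lower after scaling to the markers, which a place below every marker makes likely. The lowest of the 93 were trophoblast genes with 0 reads in KLF10AKO, Prl3b1 (-4.64), Ceacam11 (-4.15), Tpbpb (-4.05) and Tpbpa (-4.04). The 93 are thus not adipocyte genes alone. As a whole, the fixed list of fatty acid and triglyceride synthesis lay at a median of 0.02 after that scaling, with 8 genes higher and 10 lower. Among the 93 genes, Me1, malic enzyme, stood at 174 FPKM in WT and 32.9 in KLF10AKO (log2 change -2.46, -0.87 after scaling), the lipogenic gene Pnpla3 at 129 and 24.4 (-2.39, -0.81 after scaling) and Pcx, pyruvate carboxylase, at 196 and 39.998 (-2.30, -0.71 after scaling). Fasn, fatty acid synthase, stood at 88.5 and 20.9 FPKM (-2.07, -0.50 after scaling), Slc25a1, the citrate carrier, at 220.1 and 50.2 (-2.12, -0.54 after scaling) and Gpd1 at 272 and 61.5 (-2.18, -0.59 after scaling). Gpd1 is itself one of the 22 adipocyte markers, kept out of the 14 because it is also in the list of synthesis genes. The aldehyde dehydrogenase gene Aldh1a7 stood at 209 and 32.6 FPKM (-2.68, -1.09 after scaling), the matrix gene Dpt at 1082 and 242 (-2.16, -0.57 after scaling) and Fam13a at 22.8 and 3.57 (-2.52, -1.03 after scaling).

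Milk protein genes, in a list written after some were seen, were also read mainly in WT. The 7 genes had 1077 reads in WT and 41 in KLF10AKO, with Csn2 at 327 and 13 reads and Csn1s2a at 219 and 2. Lalba was the exception at 12 and 15 reads. Of the abundant placental genes, Ctsq had 119 reads in WT and 0 in KLF10AKO, Prl7d1 77 and 0, Ctsm 64 and 2, and Gcm1 0 in both groups. Afp had 7 and 265 reads and was higher in KLF10AKO (log2 change 1.53, adjusted p = 3.29e-05). H19 had 89 reads in WT and 198, 170, 392 and 8 in KLF10AKO libraries 1 to 4, high in the libraries with high skeletal muscle genes, without passing (limma adjusted p = 0.0557). Igf2 had 9 and 6 reads. Exons of Igf2 and of Ctsm each overlap those of another protein-coding gene on the same strand, so both levels are uncertain. Of the placental genes outside the trophoblast clusters with fewer reads, Plac1 had 6 and 1, Hand1 3 and 0, Tfap2c 6 and 0, and Elf5 8 and 0.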
